A study of Mus musculus with 14 samples.

How the data were processed

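Uterine implantation and decidualization sites of 14 mouse samples were taken on embryonic day 5.5, and poly(A) RNA was sequenced as single-end reads from TruSeq libraries, per the labels' protocols. The submitters' processing notes name Partek, STAR 2.4.1, Cufflinks 2.2.1, Cuffdiff 2.2.1 and the mouse build mm10, with no role or order. The annotation behind the loci and any use of strand are not given in the sources used here, so loci that overlap or share reads with a near copy cannot be separated beyond what the authors' counting did.

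The deposited table lists, per locus and read group, an estimated fragment count and an FPKM value, per the file headers, which are those of a Cuffdiff read group table. The deposited estimated counts are not whole where reads were shared out between loci: 83.5% of them were whole within a tolerance of 1e-06. The deposited FPKM values (fragments scaled by locus length and library total) carry the authors' own scaling between read groups. The other 2 columns of scaled fragments were not used here. The table has 1048576 lines, equal to the row limit of a spreadsheet sheet, and its last locus has values for 1 of the 5 conditions, so the 7710 loci with values in every read group were used. Totals and CPM values are therefore relative to these loci and not to whole libraries. Status FAIL stood at 66 entries of 6 loci, which were kept with the fragments listed. Of the locus identifiers 0 matched an identifier or symbol in the reference tables of gene names. The rule for named genes, the marker genes of cell types and the 19 gene lists fixed before the data were examined, with their camera tests, could therefore not be applied. In their place 4 loci are named, chosen after the data were seen: the 2 with the smallest p in each direction of the averaged comparison of KO with Het hosts, among loci with a mean of at least 1 CPM and ranges that do not overlap.

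The table holds 136 read groups under 5 conditions that match the 5 groups of the labels, and does not say which read groups make up a sample. Read groups were compared pairwise by a chi-square of their fragments over loci whole in every run (6121 loci with 63.2% of the fragments) and with a mean of at least 20 fragments per run. Many differed by no more than sampling noise and were counted as runs of 1 library. Run is a name used here, and whether read groups were separate sequencing runs is not known. Within each condition the 122 full-size runs were joined by average linkage into as many libraries as the labels list samples, and each of the 14 short runs, 1 per library, went to the nearest. The median chi-square per degree of freedom within a library lay between 0.989 and 1.084 over the 5 conditions. The last joins kept within a library reached 2.917 and the first between libraries 3.772. Single pairs of runs reached 3.409 within a library and started at 3.57 between libraries. Run totals were used to set the short runs aside, but not to join the full-size runs. Bands of the totals of full-size runs were disjoint between libraries in all 5 conditions. For short runs the ratio of the next library's chi-square to the nearest one's was at least 1.439. The libraries carry no animal number, so library numbers here are names only, and no pairing across groups was made. The labels give each sample its own number but no further statement on animals, so p-values measure the spread between these libraries, which may be partly technical.

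Estimated counts were summed over the runs of a library and rounded to whole numbers. The main test was edgeR 4.0.16 (R 4.3.3), its quasi-likelihood test with TMM factors, filterByExpr with the 5 groups (5576 loci kept), 1 coefficient per group, all 14 libraries in 1 fit (9 residual degrees of freedom) and a Benjamini-Hochberg adjusted p under 0.05. Fold changes are KO donor over WT donor, or the host with fewer Hoxa11 copies over the other. This design, its 9 comparisons, the correlation of donor effects and most alternatives were fixed before the data were examined. The alternatives fixed then were DESeq2 1.42.0, RLE factors, no filter on low counts, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), limma voom with sample quality weights, the compared groups alone and leaving out each library in turn. FPKM of a library was the mean of its runs weighted by fragments, with a filter at a mean FPKM of 1. Alternatives added after seeing the data left out the short runs, kept loci whole in every run, thinned every library to 5920925 fragments, and dropped the FPKM filter. The comparison of KO with Het hosts under each donor apart was added then too.

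The test was checked on simulated counts drawn from the means, library sizes and dispersions of the 5576 loci with 200 loci changed. Each locus was drawn independently, with the same dispersion in all groups, so these counts held no shift shared by many loci of a library. Among calls 5.3% were false for the donor comparison in Het hosts, 5.5% for that in KO hosts and 2.7% for KO against Het hosts. Principal components and positions of libraries used log2(CPM + 1) of 4231 loci with a mean of at least 10 CPM, computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.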

Results

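Transcript abundance was measured by RNA sequencing in 14 samples labelled as mouse uterine implantation and decidualization sites, taken on embryonic day 5.5. At such sites the embryo attaches and the surrounding stroma turns into decidua. Whether each sample, in KO hosts above all, held an embryo or decidua was not examined here. Females that were wild type (WT), heterozygous (Het) or knockout (KO) for Hoxa11, a homeobox gene of the uterine stroma, had received a bone marrow transplant from a WT or a KO donor before mating. WT hosts with WT marrow gave 3 libraries, Het hosts with WT marrow 3, Het hosts with KO marrow 3, KO hosts with WT marrow 3 and KO hosts with KO marrow 2. The deposited values end inside a locus at the row limit of a spreadsheet sheet, so any loci past that point were not seen. All counts and shares below refer to the 7710 loci before it, known by locus identifiers that the files do not pair with gene names. For that reason no gene, pathway or cell type is named here, and the level of Hoxa11 itself, which would check the genotype labels, was not analysed here.

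Over these loci a library held between 5920925 and 12589912 fragments. The totals ran from 7960283 to 12589912 in WT hosts, from 6076260 to 12157309 in Het hosts with WT marrow, from 7020458 to 12226390 in Het hosts with KO marrow, from 5920925 to 11805857 in KO hosts with WT marrow and from 6429265 to 7251564 in KO hosts with KO marrow. The most abundant locus took 6.40% ± 0.23 (SD, n = 3) of the fragments in WT hosts, 7.47% ± 1.01 (SD, n = 3) in Het hosts with WT marrow, 6.33% ± 1.12 (SD, n = 3) in Het hosts with KO marrow, 9.28% ± 0.87 (SD, n = 3) in KO hosts with WT marrow and 8.80% ± 0.74 (SD, n = 2) in KO hosts with KO marrow. A total of 5576 loci held enough fragments to be tested, and their biological coefficient of variation between libraries of a group was 22.1%.

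**Figure D1:**
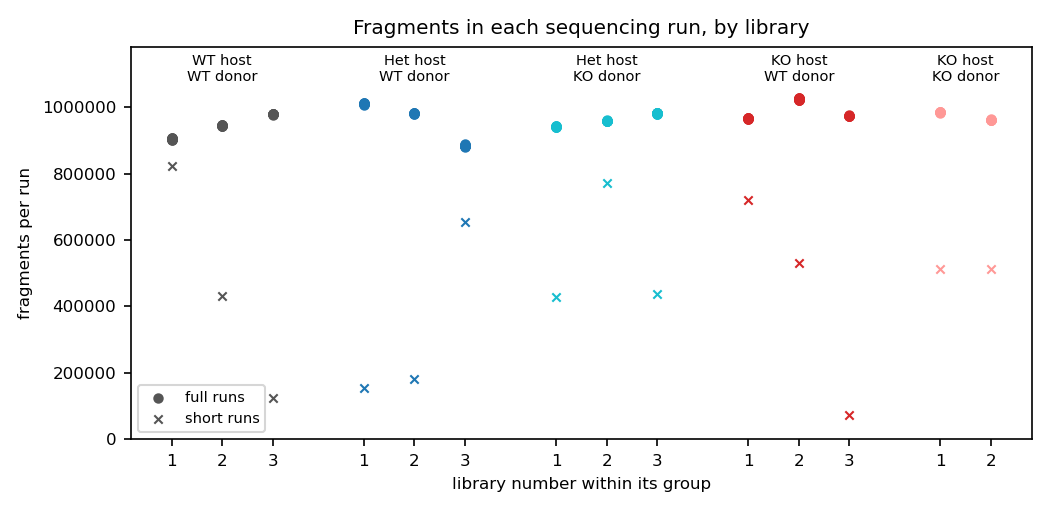
Fragments (vertical axis) in each of the 136 read groups, called runs here, placed by the library (horizontal axis) to which the run was assigned. Circles are the 122 full runs, which overlap, and crosses the 14 short runs, 1 per library. Full runs of a library lie in a narrow band, and the bands of the libraries of a group do not overlap in any of the 5 groups.

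Host genotype separated the libraries along the first principal component of log2(CPM + 1), which held 65.2% of the variance over 4231 loci with a mean of at least 10 CPM (fragments scaled to a common library total). The 5 KO host libraries scored between 29.3 and 35.4 on it, and the 9 Het and WT host libraries between -27.13 and -9.98. The second component held 8.4%. On it the 3 Het hosts with WT marrow lay at -14.77, -20.87 and 16.57, the widest scatter of any group, with the other 11 libraries between -3.21 and 7.47.

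**Figure D2:**
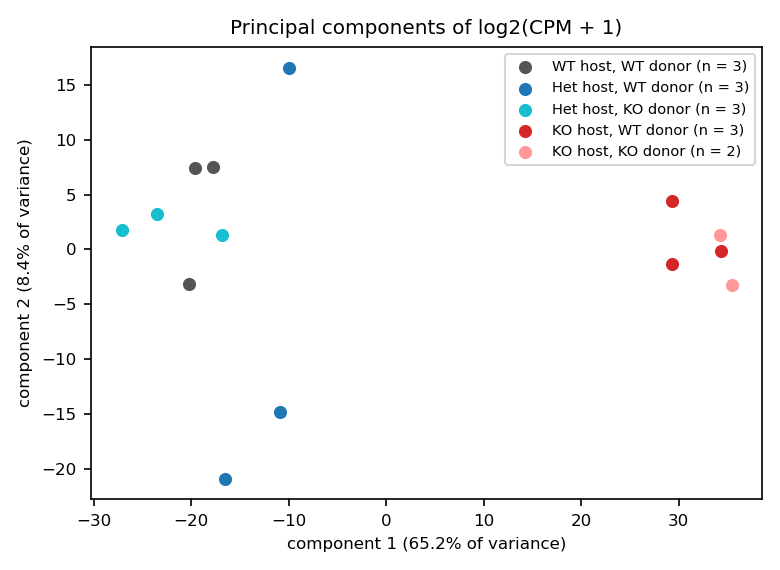
Scores of the 14 libraries on the first (horizontal, 65.2% of variance) and second (vertical, 8.4% of variance) principal components of log2(CPM + 1) over 4231 loci; each point is a library, coloured by host and donor genotype. The 5 KO host libraries stand apart on the first component, and the 3 Het hosts with WT marrow are spread on the second.

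The effect of losing Hoxa11 in the host was first read in hosts that had all received WT marrow. In KO hosts 909 loci were higher and 986 lower than in WT hosts, together 34% of the 5576 tested. The median absolute log2 fold change of the called loci was 0.85, and 396 of them rose and 398 fell by more than 2-fold. Changes of more than 8-fold were found upward at 50 loci and downward at 89. Locus XLOC_001707, 1 of 4 loci picked after their values were seen as the clearest examples of the host difference, fell from 4360 ± 806 CPM (SD, n = 3) in WT hosts to 414 ± 48.0 CPM (SD, n = 3) in KO hosts, a log2 fold change of -3.40 ± 0.19 (SE; edgeR quasi-likelihood test, adjusted p = 1.11e-06). Locus XLOC_001195 rose from 17.1 ± 1.1 CPM (SD, n = 3) to 303 ± 31.5 CPM (SD, n = 3), a log2 fold change of 4.15 ± 0.15 (SE; edgeR, adjusted p = 1.33e-08). The groups did not overlap at 1429 loci that were higher and 1536 that were lower in all KO hosts, where chance gives 10% of loci over both directions for 3 libraries against 3.

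KO hosts were next set against Het hosts, with the differences under WT and under KO marrow averaged, so that 5 libraries faced 6. Here 1326 loci were higher and 1357 lower in KO hosts, together 48.1% of those tested, with a median absolute log2 fold change of 0.66 among them. More than 2-fold changes were found at 462 loci upward and 429 downward. As a restatement of these calls in abundance, the loci called higher held 39.0% ± 1.19 (SD, n = 3) and 38.7% ± 0.26 (SD, n = 2) of fragments in KO hosts with WT and KO marrow, against 27.6% ± 1.0 (SD, n = 3) and 24.6% ± 1.46 (SD, n = 3) in Het hosts with WT and KO marrow. The loci called lower held 20.9% ± 0.69 (SD, n = 3) and 20.9% ± 0.18 (SD, n = 2) in those KO hosts, against 31.6% ± 1.51 (SD, n = 3) and 35.1% ± 1.40 (SD, n = 3) in those Het hosts. WT hosts, the only libraries outside the choice of these loci, held 25.8% ± 0.54 (SD, n = 3) in the first set and 33.7% ± 0.98 (SD, n = 3) in the second.

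The 4 example loci were picked for small p-values and ranges that do not overlap in this comparison, so their changes are larger than the median of the called loci. XLOC_001195 had a log2 fold change of 3.90 ± 0.11 (SE; edgeR, adjusted p = 4.76e-10) between KO and Het hosts, with 243 ± 4.25 CPM (SD, n = 2) in KO hosts with KO marrow against 16.2 ± 3.57 CPM (SD, n = 3) in Het hosts with KO marrow. XLOC_006767 stood at 159 ± 3.35 CPM (SD, n = 3) in KO hosts and 48.2 ± 8.1 CPM (SD, n = 3) in Het hosts with WT marrow, and its averaged log2 fold change was 1.90 ± 0.11 (SE; edgeR, adjusted p = 2.59e-07). XLOC_002678 fell from 111 ± 22.1 CPM (SD, n = 3) to 5.65 ± 1.89 CPM (SD, n = 3) under WT marrow, and from 156 ± 40.8 CPM (SD, n = 3) to 2.65 ± 0.733 CPM (SD, n = 2) under KO marrow, an averaged log2 fold change of -5.05 ± 0.22 (SE; edgeR, adjusted p = 5.76e-08). XLOC_001707 had an averaged log2 fold change of -3.25 ± 0.15 (SE; edgeR, adjusted p = 6.45e-08).

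**Figure D3:**
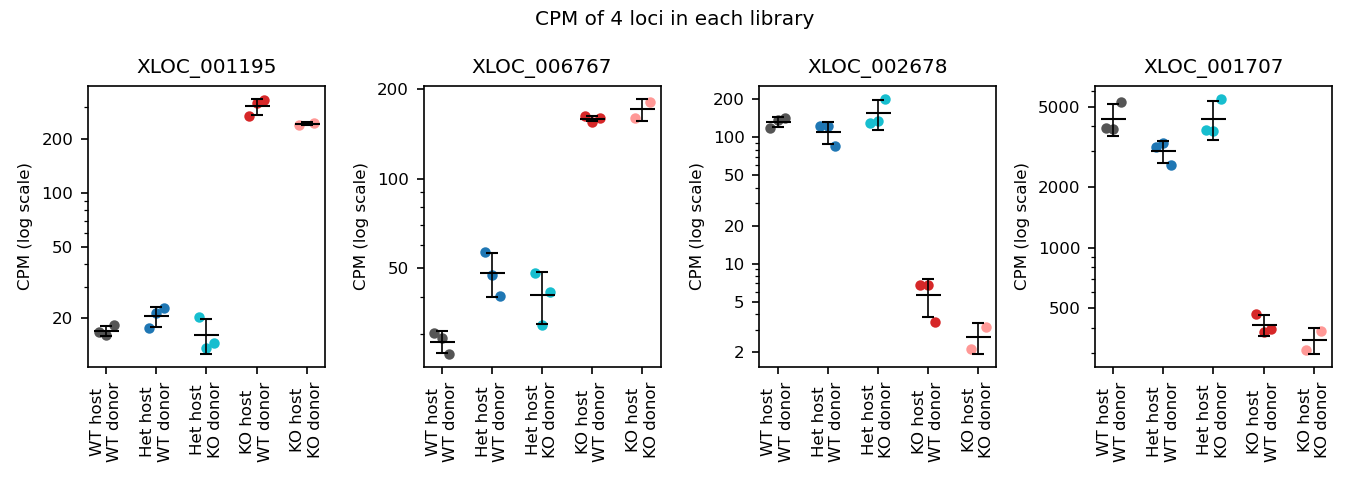
CPM (vertical axes, log scale) of 4 loci in the 14 libraries by host and donor genotype; points are libraries, horizontal bars group means and whiskers 1 SD (n = 3 per group, n = 2 for KO hosts with KO marrow). The 5 KO host libraries lie above all others at XLOC_001195 and XLOC_006767 and below all others at XLOC_002678 and XLOC_001707, under either donor.

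Loci with at least 1 CPM in every library of one side and at most 3 fragments in every library of the other were rare. In the comparison of KO with Het hosts 15 loci were present in Het hosts alone and 0 in KO hosts alone. In that of KO with WT hosts under WT marrow the numbers were 28 loci in WT hosts alone and 3 in KO hosts alone. Between donors in KO hosts 3 loci were present with WT marrow alone and 0 with KO marrow alone (n = 2). None of these 3 passed the adjusted threshold. Between donors in Het hosts the numbers were 0 and 0.

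The host difference was also estimated apart under each donor, from libraries that share none. With WT marrow 741 loci were higher and 879 lower in KO than in Het hosts, and with KO marrow 1048 were higher and 1019 lower. The calls shared 626 loci upward and 721 downward, where independent lists would share 139.3 and 160.6, and 2 loci were called in opposite directions. Across the 5576 loci, which are not independent replicates, the log2 fold changes had a Pearson r of 0.759 and a Spearman rho of 0.777, with the same sign at 81.8%.

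KO hosts with KO marrow, labelled Hoxa11 KO for both host and donor, were compared with WT hosts with WT marrow. In them 854 loci were higher and 879 lower, together 31.1% of those tested, with a median absolute log2 fold change of 0.95. XLOC_002678 stood at 133 ± 11.9 CPM (SD, n = 3) in WT hosts and had a log2 fold change of -5.63 ± 0.36 (SE; edgeR, adjusted p = 2.25e-06). XLOC_006767, at 28.4 ± 2.39 CPM (SD, n = 3) in WT hosts and 171 ± 14.9 CPM (SD, n = 2) in these KO hosts, rose by a log2 fold change of 2.59 ± 0.17 (SE; edgeR, adjusted p = 2.25e-06). The group of 2 limited this count: without its library 1 the number of called loci was 1079, and without its library 2 it was 1122, against 1733 with both.

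**Figure D4:**
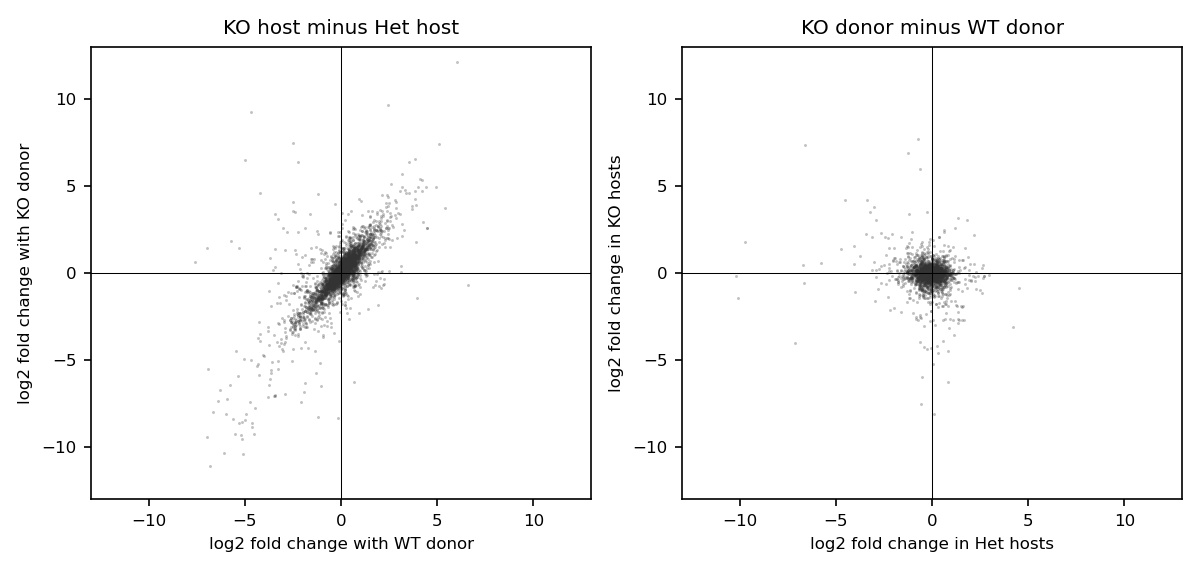
Log2 fold changes of 5576 loci, each point a locus. Left, KO minus Het hosts under WT marrow (horizontal) and KO marrow (vertical), which lie along a rising diagonal (Pearson r = 0.759); right, KO minus WT marrow in Het hosts (horizontal) and in KO hosts (vertical), which show no such line (Pearson r = -0.134).

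Loss of a single host copy of Hoxa11 was read from Het against WT hosts, all with WT marrow. No locus passed the threshold (0 of 5576 by edgeR, smallest adjusted p = 0.0707). At an unadjusted p under 0.05 there were 366 loci, a number that was 1024 without Het host, WT donor library 3, 242 without WT host library 2 and 202 without WT host library 3. Without any difference a share of 0.05 of the 5576 loci would pass this unadjusted threshold, here and in the comparisons below. DESeq2 called 15 loci and limma voom with sample quality weights 7. The 95% interval of the log2 fold change lay inside 2-fold either way at 75% of loci. Leaving out Het host, WT donor library 3 brought the edgeR count to 28, with 18 loci higher and 10 lower. XLOC_006767 stood at 48.2 ± 8.1 CPM (SD, n = 3) in these Het hosts against 28.4 ± 2.39 CPM (SD, n = 3) in WT hosts, a log2 fold change of 0.76 ± 0.15 (SE; edgeR, adjusted p = 0.258).

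Het hosts with KO marrow were likewise set against WT hosts with WT marrow, and 0 of 5576 loci passed by edgeR (smallest adjusted p = 0.092). At an unadjusted p under 0.05 there were 383 loci, and 249 without Het host, KO donor library 3 or 240 without WT host library 2. DESeq2 called 26 and limma voom with quality weights 12. The 95% interval lay inside 2-fold at 75.5% of loci. Leaving out Het host, KO donor library 2 gave 1 locus by edgeR.

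The donor comparisons ask whether the Hoxa11 genotype of the transplanted marrow changes transcript abundance at the tested loci in the same kind of host. In Het hosts 0 loci passed by edgeR between KO and WT marrow (smallest adjusted p = 0.113), with the 95% interval inside 2-fold at 72.2% of loci. At an unadjusted p under 0.05 there were 866 loci, but another split of the same 6 libraries gave 868, and with 1 library left out the number ran from 430 (without Het host, KO donor library 3) to 1252 (without Het host, WT donor library 3). The count of calls depended on a single library and on the tool. Without Het host, WT donor library 3, edgeR called 147 loci, 86 higher and 61 lower with KO marrow. The donor effect in KO hosts had the same sign at 57.1% of these 147 loci, with a Pearson r of -0.288 across them. DESeq2 called 168 with all libraries, 91 higher and 77 lower. Limma voom with sample quality weights called 155, and gave Het host, WT donor library 3 the lowest weight of the 14 (0.281). In the same group library 1 had the highest weight of the 14 (2.032) and library 2 had 0.439. The voom mean of Het hosts with WT marrow thus rested mostly on library 1. The 4 example loci of the host difference had log2 fold changes between KO and WT marrow in Het hosts of -0.36 ± 0.15 (SE) for XLOC_001195, -0.24 ± 0.15 (SE) for XLOC_006767, 0.49 ± 0.22 (SE) for XLOC_002678 and 0.54 ± 0.18 (SE) for XLOC_001707, none past the threshold.

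In KO hosts 0 loci passed by edgeR between KO marrow (n = 2) and WT marrow (n = 3), with a smallest adjusted p of 0.572. At an unadjusted p under 0.05 there were 120 loci, fewer than the share of 0.05 of tested loci that would pass without any difference. DESeq2 called 2 loci and limma voom with quality weights 0. The 95% interval lay inside 2-fold at 73.3% of loci. At XLOC_001195 the means were 243 ± 4.25 CPM (SD, n = 2) with KO marrow and 303 ± 31.5 CPM (SD, n = 3) with WT marrow, a log2 fold change of -0.32 ± 0.15 (SE; edgeR, adjusted p = 1). The other example loci had log2 fold changes of 0.1 ± 0.16 (SE) for XLOC_006767, -1.12 ± 0.37 (SE) for XLOC_002678 and -0.25 ± 0.2 (SE) for XLOC_001707, none past the threshold.

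Averaged over Het and KO hosts, the donor comparison gave 0 loci by edgeR (smallest adjusted p = 0.575), 427 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma voom with quality weights. Without Het host, WT donor library 3 the unadjusted count was 786. The 95% interval lay inside 2-fold at 83.3% of loci. The test of whether the donor effect differed between KO and Het hosts gave 0 loci by edgeR (smallest adjusted p = 0.428), 411 at an unadjusted p under 0.05, 25 by DESeq2 and 0 by limma voom with quality weights. Without Het host, WT donor library 3 edgeR called 2 loci in that test, with 690 at an unadjusted p under 0.05, and without Het host, KO donor library 3 the unadjusted count was 270. Across 5576 loci, which are not independent replicates, the donor effects in Het and in KO hosts, from libraries that share none, had a Pearson r of -0.134 and a Spearman rho of -0.016, with the same sign at 50% of loci. Without KO host, KO donor library 1 the Pearson r was -0.045, the rho -0.113 and the same-sign share 46.1%. Without library 2 they were -0.015, 0.106 and 55.7%, so the sign of rho turned on which library of that pair was kept. With log2(FPKM + 1) differences in place of the edgeR fold changes the Pearson r was -0.242 and the rho -0.042.

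On simulated counts with the depth and spread of these libraries, the test recovered 22.4% of loci changed 1.5-fold, 53.7% of those changed 2-fold and 84.8% of those changed 4-fold for the donor comparison in Het hosts. For the donor comparison in KO hosts the shares were 25.4%, 47.8% and 81.8%, and for KO against Het hosts 55.2%, 77.6% and 86.4%. The simulated counts held no shift shared by many loci of a library, so these shares may be too high where a library stands apart.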

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

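The settings without short runs, with loci whole in every run, with thinned libraries and with the unfiltered FPKM values were chosen after seeing the data. The 3 comparisons of KO hosts with WT or Het hosts kept counts within 1.5 times under all 11 settings other than left-out libraries: from 1441 to 2362 against WT hosts under WT marrow, from 2003 to 2867 against Het hosts, and from 1306 to 1947 for KO hosts with KO marrow. With libraries left out they ran from 1455 to 1621, from 2332 to 2804, and from 1079 to 1470; the last moved by over 1.5 times only without a library of the group of 2, where the lone library was assumed to vary like the other groups. The 4 named loci were called in the same direction in all 86 values (adjusted p up to 3.5e-06), which their choice by small p favours and which says nothing of other loci. XLOC_006767 and XLOC_002678 have no value in the setting with loci whole in every run, so that setting does not check them. The log2 fold change of XLOC_002678 was -3.21 on log2(FPKM + 1), against -5.05 in the main test.

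Counts of 0 moved as follows, and the cause was not tested. DESeq2 gave 168 loci for the donor effect in Het hosts, 2 in KO hosts, 3 averaged over both, 25 for the interaction, 15 for Het against WT hosts and 26 for Het hosts with KO marrow against WT hosts. Voom with quality weights gave 155 for the donor effect in Het hosts, 7 for Het against WT hosts and 12 for Het hosts with KO marrow against WT hosts. On log2(FPKM + 1) limma gave 2 for the donor effect in Het hosts, 1 in KO hosts, 1 for the interaction and 1 for Het hosts with KO marrow. On log2(FPKM + 0.1) it gave 2, 1, 1 and 1 for these, and 1 for the averaged donor effect. Without a filter on FPKM it gave 1, 7, 1 and 5 for these, and 3 for Het against WT hosts. Loci whole in every run gave 2 for Het against WT hosts, and the compared groups alone 1 for Het hosts with KO marrow.

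With libraries left out the donor effect in Het hosts ran from 0 to 147, the interaction from 0 to 2, Het against WT hosts from 0 to 28 and Het hosts with KO marrow against WT hosts from 0 to 1; the donor effect in KO hosts and that averaged over both stayed at 0. Pearson r between the donor effects was -0.242 on log2(FPKM + 1) and ran from -0.155 to -0.015 with libraries left out. The camera test with an estimated correlation was not run, since loci carry no gene names. No paired analysis was possible because the libraries carry no animal number. At this depth and spread, 53.7% of simulated 2-fold and 84.8% of simulated 4-fold changes were recovered in the donor comparison of Het hosts. Changes of these sizes, and smaller ones more often, can therefore be missed.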

Other observations

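The tests of library depth and of shared reads for the host difference, the tests of short loci and of a wrong label, the order of the Het libraries, the splits compared by unadjusted p and the positions along the line between hosts were chosen only after the results were seen.

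The 2683 loci called between KO and Het hosts were 48.1% of those tested, a breadth that invites a technical account. A difference in depth as its source is argued against by library totals that overlap between KO hosts (5920925 to 11805857) and Het hosts (6076260 to 12226390), and by thinning every library to 5920925 fragments, which left no difference in totals and still 2601 loci called. Reads shared out between loci are argued against by the loci with whole fragment counts in every run, of which 49.5% were called. Chance in the split of the libraries within donors is argued against, since 1 of 100 splits, the real one, gave as many. That is the smallest share these splits allow, and the highest count of the others was 1953. For KO against WT hosts under WT marrow the 10 splits are too few for a share under 0.05; the real count was 1895 and the highest other 0. Another mix of cell types in the tissue stays open and cannot be told apart from changes within cells, because 0 locus identifiers are paired with a gene name. A broad effect of host Hoxa11 on the implantation site may be the biological counterpart, and was not tested beyond the group comparison.

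The donor effect in Het hosts turned on Het host, WT donor library 3, with 0 loci called by edgeR in its presence and 147 without it, while DESeq2 called 168 and limma voom with quality weights 155 with it. This library lay at a root mean square distance of 0.551 (log2 scale) from the mean of the other 2 libraries of its group, against 0.4 and 0.464 for those. From the WT host mean those 2 lay further (0.401 and 0.475) than this library (0.349). Which libraries of the group deviate is therefore not settled by these distances. The depth of that library was 12157309 fragments. With every library thinned to the lowest total, edgeR still called 0 of 5459 loci, with 821 at an unadjusted p under 0.05. Thinning can itself lower the number of calls, so this count does not decide whether a difference in depth was the cause. A thinned count without that library was not made. Its distance after thinning, 0.555, decides nothing, since thinning adds noise and can hardly lower such a distance. An excess of fragments in short loci was measured in library 3: the tenth of tested loci with the highest FPKM per CPM held 4.53% of its fragments, against 2.66% to 3.74% in the other 13 libraries. The lowest shares, 2.9% and 2.66%, were those of the other 2 libraries of its group. Without those 558 loci of the tenth the count was still 0 with all libraries and 143 without library 3, which argues against these loci alone as the cause. A shift with locus length over all loci was not tested and stays open. A WT host library under a Het label may be behind the change in calls and cannot be told apart from a Het host that varies. The distance of library 3 from the WT host mean was 0.349, but the 3 Het hosts with KO marrow lay as near (0.284 to 0.341) as the WT host libraries themselves (0.286 to 0.36), so this distance does not mark a WT host. The position of library 3 between WT and KO hosts, 0.178, was outside the 0.019 to 0.085 of WT hosts. Between Het and WT hosts edgeR called 0 loci with this library and 28 without it.

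On the line from the WT host mean (0) to the KO host mean (1), each library left out of its own group's mean, Het hosts with WT marrow lay at 0.159 ± 0.048 (SD, n = 3) and Het hosts with KO marrow at -0.017 ± 0.097 (SD, n = 3), with no overlap of the 6 libraries. WT hosts lay at 0.052 ± 0.033 (SD, n = 3). The hypothesis is that donor genotype may shift Het hosts along the host axis, with KO marrow on the WT side. The exact permutation p (two-sided) was 0.1, the smallest that 3 libraries against 3 can give, and 0.15 after adjustment over 3 comparisons, so a chance order of the 6 libraries cannot be told apart from a donor effect. KO hosts gave the reverse order, 1.018 ± 0.014 (SD, n = 2) with KO marrow and 0.935 ± 0.074 (SD, n = 3) with WT marrow, with ranges that overlap.

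For the comparisons with 0 loci called, every split gives as many, so other splits were compared by loci at an unadjusted p under 0.05. For the donor effect averaged over Het and KO hosts, 20 of 100 splits within hosts gave as many as the real 427, with 678 as the highest of the others, so chance cannot be excluded. For the 3 comparisons of 3 libraries against 3 the 10 splits are too few for a share under 0.05. The donor effect in Het hosts had 866 such loci against 868 in the highest other split, and 2 of the splits gave as many. Het against WT hosts had 366 against 928, and 5 of the splits gave as many; with 1 library left out the 366 ran from 202 to 1024, the latter without Het host, WT donor library 3. Het hosts with KO marrow against WT hosts had 383 against 422, and 2 of the splits gave as many. At the adjusted threshold the highest counts of other splits were 28 loci for the averaged donor effect and 15 for Het against WT hosts, and what sets those libraries apart was not tested.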
